A study of Mus musculus with 6 samples.

How the data were processed

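The series holds bulk RNA sequencing of mouse naive CD4+ T cells from the spleen of C57BL/6 animals, exposed in culture to NETs or to vehicle. NETs, or neutrophil extracellular traps, are webs of DNA, histones and granule proteins that neutrophils release. Per the labels' protocols, the cells were kept for 72 h with beads that engage CD3 and CD28, with IL-2 and with antibodies that block interferon-gamma and IL-4. RNA was purified on RNeasy columns and libraries followed standard Illumina protocols, per the labels' protocols. The source of the NETs and their dose are not given in the sources used here. There were 3 NETs libraries and 3 vehicle libraries, grouped by their treatment labels and numbered by their titles. Nothing states that the replicates came from separate animals or cultures, so p-values measure the spread between these samples only, which may be technical.

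The authors deposited whole-number read counts per Ensembl gene, with no normalization, for 54532 genes. A second deposited count table with gene annotation held identical values. The submitters' processing notes name STAR and DESeq2 without versions and the genome build mm9. The counting program, the annotation release, the filters and any use of strand are not given in the sources used here. Of the 54495 genes also found in the reference annotation of build GRCm38, 53585 (98.3%) had the same chromosome, start and end in the deposited table. Coordinates below are therefore those of the deposited table and are those of GRCm38, although the notes name mm9. Without knowledge of strand use, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as histone, H2-Q, guanylate-binding and ribosomal protein genes, are uncertain.

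The authors also deposited FPKM values, which per the file headers and the values are reads divided by a gene length and by the library's reads counted in genes. The length divided by was worked out for 10270 genes. It equalled the deposited gene length within 1% for 11.3% of them and was shorter for 88.7%, with a median ratio of 0.396. FPKM was used only for alternatives to the count test.

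Total counts per library ranged from 15657622 to 18655997. The genes tested were those kept by edgeR's filterByExpr with the 2 groups, 13900 genes, and 0.135% of reads lay outside them. Genes with no read in any library numbered 29752. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, two-sided, group as the only term) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change had a median of 0.146 over all genes tested and 0.119 over the 10081 genes with a mean of at least 5 CPM (counts scaled to the library's total). The common biological coefficient of variation was 0.134. CPM values in the text use a library's total counts without the TMM factor. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. A gene with 0 reads in a group was given a floor of 3 counts over the group.

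For gene groups, 48 lists were fixed with 1070 gene symbols, of which 1068 were matched to the table. They covered respiratory chain complexes, metabolism, T cell states, cell cycle, stress and innate responses, markers of other cell types and RNA quality. Each list was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 48 lists. Camera was repeated with a correlation estimated for each list, and the directional rotation test fry was run. Counts of list members are also given adjusted over the list alone. A list score in a library is the mean over its tested members of log2 CPM minus the vehicle mean. Scores and shares were compared by two-sided exact permutation tests, which with 3 against 3 libraries cannot go below 0.1.

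The genes to be named followed a rule. It took (a) every gene of a panel of 24 genes of T cell fate, cytokines, NETs sensing and metabolism. It took (b) the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold. These needed a mean CPM of at least 5, NETs libraries all beyond the vehicle libraries, and a symbol that is not provisional. With fewer than 5 in a direction, the 5 with the smallest p that met the other conditions were taken and said not to pass. It took (c) up to 4 members with the smallest p of each list past the camera threshold, and of the oxidative phosphorylation and regulatory T cell lists whatever their test. The rule gave 130 genes, of which 124 were tested; a few of them are not reported here. The design, the lists, this rule and the first set of alternatives were fixed before the data were examined.

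The gene test was tried on simulated counts drawn from the means and library sizes of these 6 libraries, on 13567 genes. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery below that level was not tried. At a 2-fold change it recovered 58 of 66 changed genes (87.9%), at 1.5-fold 40 of 67 (59.7%) and at 1.25-fold 12 of 67 (17.9%). Of 122 genes it called, 12 had not been changed. In another simulation, on 13581 genes, with no change camera called 0 of 47 lists and edgeR 0 genes. A list raised by 0.2 on the log2 scale came out at a median of 0.21 with an adjusted p of 1.41e-29, and 0.00481 with an estimated correlation. All simulated genes were drawn independently, whereas the lists had a median estimated correlation of 0.132 in the data. The simulation therefore could not show false list calls that arise from genes varying together.

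Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter on low counts (all genes with a read), a filter of CPM of at least 5 in 3 libraries, the replicate number as a block, and each library left out in turn. Other tools were the DESeq2 1.42.0 Wald test, limma-voom, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1). A minimum absolute log2 fold change of 1 was also tried. For the lists, a trend of the gene statistics with the deposited gene length was removed, with and without the block. Removal of a trend with transcript GC content, removal of both trends, camera on the gene statistics with no trend removed (the reference for these), and a fit on protein-coding genes only were added after seeing the data. Pairs of libraries of 1 group differed by more than sampling noise, with chi-square per degree of freedom from 9.75 to 18.3, so none was counted as a copy of another. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.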

Results

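The transcriptomes of naive CD4+ T cells, stimulated for 72 h through CD3 and CD28 in the presence of IL-2, were compared between 3 libraries from cells exposed to NETs and 3 from cells exposed to vehicle. Read depth was similar across the 6 libraries, at 18655997, 15657622 and 16086211 counts in vehicle replicates 1 to 3 and 17170867, 18394828 and 17148910 counts in NETs replicates 1 to 3. TMM scaling factors lay between 0.988 and 1.01. The first 2 principal components held 32.9% and 21.7% of the variance. On the first, vehicle replicate 3 lay at 11.4, beside NETs replicate 2 at 11.9 and beyond NETs replicate 3 at 0.177, so the groups did not separate on it. Protein-coding genes took 98.1% ± 0.108 of counts in vehicle and 98.2% ± 0.113 in NETs libraries (SD, n = 3 each; exact permutation p = 0.5).

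The first question was which single genes NETs changed. The genes with the smallest p-values that were higher with NETs included Atp5g3 and Ndufb8, subunits of ATP synthase and of respiratory complex I, Sdhd, a membrane anchor of complex II, Nudt1, an enzyme that clears oxidised nucleotides, and Dusp4, a phosphatase that acts on MAP kinases. Those lower with NETs included Lyst, a regulator of lysosomal trafficking, Gbp4, an interferon-inducible GTPase, H2-Q5, a non-classical MHC class I gene, and the nuclear proteins Zmym5 and Arid4b. None of these 10 genes passed the threshold over all genes. Atp5g3 (ENSMUSG00000018770; chromosome 2, 73908447 to 73911326) averaged 112 ± 14.8 CPM with vehicle and 163 ± 18.6 CPM with NETs (SD, n = 3 each), a 1.47-fold difference with a log2 fold change of 0.56 (SE 0.11) and an edgeR adjusted p of 0.223. Lyst (ENSMUSG00000019726; chromosome 13) averaged 125 ± 3.7 CPM with vehicle and 87.7 ± 3.39 CPM with NETs, a log2 fold change of −0.50 (SE 0.08; adjusted p = 0.170). The log2 fold changes of the other higher genes were 0.73 for Dusp4, 0.72 for Nudt1, 0.55 for Ndufb8 and 0.41 for Sdhd. Those of the other lower genes were −0.68 for H2-Q5, −0.60 for Gbp4, −0.44 for Zmym5 and −0.40 for Arid4b. All 8 had an adjusted p of 0.223.

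By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13900 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.170. At an unadjusted p under 0.05 there were 1776 genes, 934 higher and 842 lower, where chance alone gives about 695. Another split of the libraries gave more, as setting vehicle replicates 1 and 2 and NETs replicate 3 against the other libraries gave 2159 such genes. Leaving out a library moved it from 435 higher and 434 lower (without NETs replicate 1) to 1578 higher and 1364 lower (without vehicle replicate 3). The 3 NETs libraries lay wholly above or below the 3 vehicle libraries in 2304 genes (16.6%, against 10% by chance). With no filter on low counts edgeR called 322 genes (192 higher, 130 lower), and DESeq2 called 130 (62 higher, 68 lower). Limma-voom called 1 gene, S100a9, a calcium-binding protein abundant in neutrophils, and limma-trend on FPKM called 1 gene at each pseudocount, Gm24270, a 57-base gene of the miRNA class. Gm24270 was named after its values were seen. Without vehicle replicate 3, edgeR called 405 genes (218 higher, 187 lower). Without NETs replicate 1 it called 1 (Gm23935), and without NETs replicate 2 it called 2 (Lsm4 and Gm23935), genes that were likewise named after their values were seen.

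**Figure D1:**
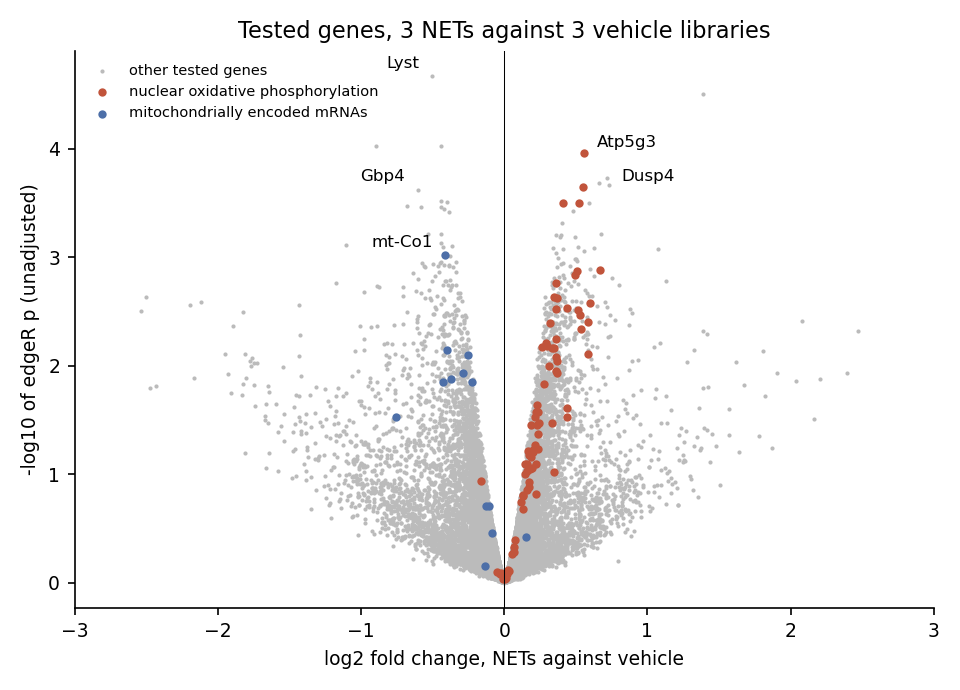
Log2 fold change (NETs against vehicle, x axis) against −log10 of the unadjusted edgeR p (y axis) for the tested genes, with 5 genes beyond ±3 left out. Nuclear oxidative phosphorylation genes lie mostly to the right (74 of 79 above 0) and mitochondrially encoded mRNAs mostly to the left (12 of 13 below 0).

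Nuclear genes of oxidative phosphorylation were higher as a group in the cells exposed to NETs by camera with the preset correlation (adjusted p = 3.03e-23), but the adjusted p was 0.246 with an estimated correlation. Of 79 measured subunits, 74 had a log2 fold change above 0, and the list's median was 0.23. All 5 respiratory complexes shared the direction, with medians of 0.24 for complex I (36 genes), 0.25 for complex II (4 genes), 0.19 for complex III (9 genes), 0.21 for complex IV (12 genes) and 0.28 for ATP synthase (17 genes). Examples from complex I, which oxidises NADH, were Ndufa1 (log2 fold change 0.67, SE 0.17), Ndufb6 (0.51, SE 0.13) and Ndufa8 (0.49, SE 0.13). In complex II, which also serves the TCA cycle, Sdha stood at 0.27, Sdhb at 0.23 and Sdhc at 0.22. Complex III genes included Uqcr11 (0.58), Uqcrq (0.36), Uqcr10 (0.30) and Cyc1 (0.23), and complex IV genes Ndufa4 (0.37), Cox5a (0.36), Cox7a2 (0.34) and Cox6a1 (0.32). Among ATP synthase subunits, Atp5k was at 0.54, Atp5e at 0.52 and Atp5j at 0.36.

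By complex, the camera adjusted p was 4.46e-14 for complex I, 0.000281 for complex II, 0.00032 for complex III, 1.88e-05 for complex IV and 1.19e-08 for ATP synthase. With an estimated correlation the adjusted p was 0.246 for complexes I and IV and ATP synthase, and 0.269 for complexes II and III. Of the 79 subunits, 31 were higher when adjusted over the list alone, and 0 when adjusted by edgeR over all genes, with 42 at an unadjusted p under 0.05. Within the complexes, adjusted over the list alone, 13 genes of complex I, 3 of complex II, 3 of complex III, 4 of complex IV and 8 of ATP synthase were higher, and over all genes 0 in each. The list score was −0.01, −0.06 and 0.06 in the vehicle libraries and 0.34, 0.19 and 0.24 in the NETs libraries. It averaged 0.26 ± 0.07 with NETs, against an SD of 0.06 around 0 with vehicle (n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

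The 13 mRNAs encoded by the mitochondrial genome went the other way by camera (adjusted p = 3.39e-06 with the preset and 0.246 with an estimated correlation). Their median log2 fold change was −0.25, with 12 of 13 below 0. The transcript mt-Co1, for the catalytic core of complex IV, averaged 8248 ± 682 CPM with vehicle and 6142 ± 740 CPM with NETs (SD, n = 3 each), a log2 fold change of −0.41 (SE 0.10; edgeR adjusted p = 0.223). The values were −0.40 for mt-Co2, −0.29 for mt-Cytb and −0.25 for mt-Nd6. With vehicle, mt-Co2 averaged only 31.3 CPM, against 2875 CPM for mt-Cytb and 314 CPM for mt-Nd6, and the cause of its low level was not tested. Reads on mitochondrial genes made up 1.66% ± 0.055 of all counts with vehicle and 1.34% ± 0.134 with NETs (exact permutation p = 0.1). In this list 8 genes were lower when adjusted over the list alone, and over all genes 0 by edgeR, with 8 at an unadjusted p under 0.05. Removing a trend of the statistics with transcript GC content moved the median to −0.10 (adjusted p = 0.00722).

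Other mitochondrial and metabolic lists were also higher with NETs by camera with the preset correlation, but with an estimated correlation the adjusted p was 0.246 for the mitochondrial ribosome, 0.270 for the TCA cycle and fatty acid oxidation, and 0.391 for cholesterol synthesis. The mitochondrial ribosome had 59 of 69 genes above 0 and a median of 0.19, with Mrpl41 at 0.52, Mrpl2 at 0.47, Mrpl13 at 0.46 and Mrpl34 at 0.34. Among 22 TCA cycle genes, which feed electrons to the respiratory chain, 21 lay above 0 with a median of 0.16, including Fh1 (0.28). Genes of fatty acid oxidation had a median of 0.10 over 19 genes, with Acadvl at 0.39, Cpt2 and Etfa each at 0.33 and Hadha at 0.22. Cholesterol synthesis genes had a median of 0.16 over 24 genes, among them Pmvk (0.33), Cyp51 (0.27) and Sqle (0.23). All 4 lists shifted upward by camera, with an adjusted p of 2.63e-10 for the mitochondrial ribosome, 2.84e-06 for the TCA cycle, 0.00141 for fatty acid oxidation and 0.000214 for cholesterol synthesis, whose scores overlapped between groups (exact permutation p = 0.2, and 0.1 for the other 3). The TCA gene Sdhd was higher when adjusted over the list alone, 1 gene of 22, and 0 genes of the other 3 lists passed that test. Over all genes edgeR called 0 in each, with 22, 7, 5 and 7 genes at an unadjusted p under 0.05.

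Glycolysis and cytosolic ribosome genes lay slightly above 0 as lists. Glycolytic genes had a median of 0.06, with 15 of 23 above 0, and examples were Ldha, which makes lactate (0.40, SE 0.11), Pkm (0.33), Pfkl (0.32) and Pgam1 (0.27). Cytosolic ribosomal proteins had a median of 0.05, with 51 of 78 above 0, and examples were Rps2 (0.39), Rps29 (0.36) and Rplp1 (0.28). Camera gave an adjusted p of 0.0205 for glycolysis and 0.0184 for ribosomal proteins, and the adjusted p was 0.641 and 0.782 with an estimated correlation. In both lists 0 genes passed when adjusted over the list alone or over all genes by edgeR, with 9 and 12 genes at an unadjusted p under 0.05. The scores overlapped between groups in both (exact permutation p = 0.4 each). The glycolysis call was lost without vehicle replicate 3 (adjusted p = 0.225), NETs replicate 1 (0.119) or NETs replicate 2 (0.327), and the ribosomal call without vehicle replicate 3 (0.750) or NETs replicate 3 (0.161). Both calls also ended with the GC trend removed (0.0875 and 0.0508), among protein-coding genes only (0.051 and 0.0878) and with a filter of CPM of at least 5 (0.0592 and 0.0516). The ribosomal call ended with the length trend removed (0.0993), and both ended with that trend removed under the replicate block (0.056 and 0.168). With the length and GC trends removed the ribosomal median was −0.016.

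**Figure D2:**
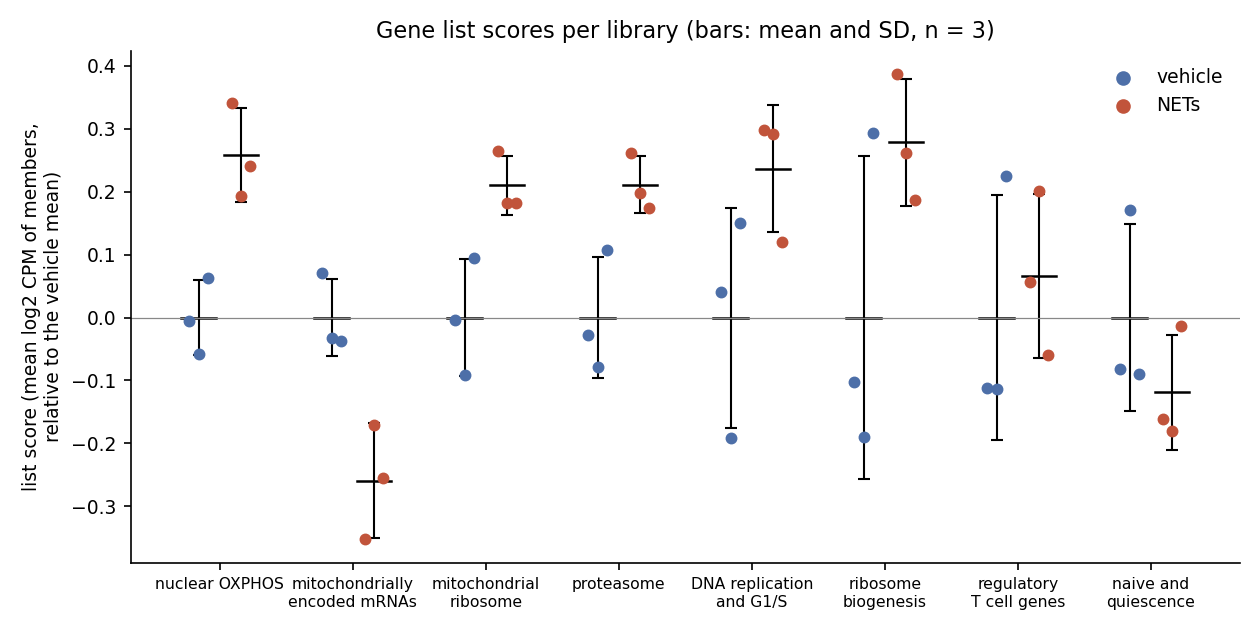
List score per library (y axis, mean log2 CPM of a list's tested members relative to the vehicle mean) for 8 gene lists, with bars for the mean and SD of 3 libraries per group. Nuclear oxidative phosphorylation scores of the NETs libraries (0.19 to 0.34) lie above all vehicle scores, while regulatory T cell scores overlap.

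Lists of ribosome biogenesis, the proteasome and DNA replication were higher with NETs by camera with the preset correlation, but with an estimated correlation their adjusted p was 0.401, 0.269 and 0.373. Ribosome biogenesis and Myc target genes had a median of 0.29, with 33 of 38 above 0, including Rrs1 (0.68, SE 0.16), Gar1 (0.54), Nhp2 (0.46) and the snoRNP methyltransferase Fbl (0.42). Proteasome genes had a median of 0.21 with 34 of 36 above 0, and the values of the catalytic-ring subunits were 0.48 for Psmb6, 0.41 for Psmb7, 0.39 for the immunoproteasome subunit Psmb8 and 0.34 for Psmb4. DNA replication genes had a median of 0.22 with 36 of 38 above 0, among them the replication factor Gins2 (0.52), cyclin Ccne1 (0.37), the sliding clamp Pcna (0.35) and Rpa2 (0.34). By camera the adjusted p was 1.85e-09, 4.83e-13 and 2.44e-13 for these 3 lists. Adjusted over the list alone, 5, 10 and 10 genes were higher, and 0 in each over all genes by edgeR, with 12, 16 and 18 at an unadjusted p under 0.05. The exact permutation p of the scores was 0.3 for ribosome biogenesis, 0.1 for the proteasome and 0.2 for replication, and vehicle replicate 3 scored above NETs replicate 3 on ribosome biogenesis (0.29 against 0.19) and on replication (0.15 against 0.12).

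Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had a median of 0.64 over 11 measured genes, with Hist1h2bg at 1.82, Hist1h2ag at 1.39, Hist1h2ae at 1.16 and Hist1h3c at 1.04, all at under 5 CPM. The list's camera adjusted p was 0.00739, and 0.269 with an estimated correlation. Of the histone genes, adjusted over the list alone, 2 (Hist1h2ag and Hist1h3c) were higher, and over all genes 0 by edgeR, with 4 at an unadjusted p under 0.05. Without vehicle replicate 3 the histone call was lost (0.127), as it was with the GC trend removed (0.0508). Mitosis genes lay slightly lower, with a median of −0.06 and 28 of 40 below 0. Anln, a scaffold of the cleavage furrow, stood at −0.42, Ckap2 at −0.27 and Cenpe at −0.26, while Cks2 stood at 0.21. The mitosis list had a camera adjusted p of 0.0138 and an adjusted p of 0.681 with an estimated correlation, and 0 genes passed when adjusted over the list alone or over all genes by edgeR, with 7 at an unadjusted p under 0.05. Its scores had an exact permutation p of 0.3, and its call was lost without vehicle replicate 2 (0.128) or NETs replicate 1 (0.281).

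Stress and cytokine response lists were higher with NETs by camera with the preset correlation, but with an estimated correlation the adjusted p was 0.384 for the integrated stress and unfolded protein responses, 0.246 for oxidative stress and 0.584 for the IL-2 and STAT5 response. Genes of the integrated stress and unfolded protein responses had a median of 0.12 over 31 genes, including the chaperone cofactor Sdf2l1 (0.60), Phgdh (0.41), the transcription factor Xbp1 (0.35) and Pdia6 (0.35). Oxidative stress genes had a median of 0.13 over 28 genes, with thioredoxin Txn1 at 0.34, Tkt at 0.22 and Prdx2 and Ftl1 each at 0.20. The IL-2 and STAT5 response had a median of 0.12 over 23 genes, with Osm at 0.35, Socs1 at 0.29, Ccnd3 at 0.28 and the receptor subunit Il2rb at 0.23. Camera placed them upward at an adjusted p of 0.00451, 0.00591 and 0.0347. There were 3 genes of the first list (Sdf2l1, Xbp1 and Pdia6) higher when adjusted over the list alone and 0 of the others, and over all genes edgeR called 0 in each, with 8, 4 and 6 at an unadjusted p under 0.05. The scores overlapped between groups in all 3 lists (exact permutation p = 0.3, 0.2 and 0.5), and vehicle replicate 3 had the highest IL-2 and STAT5 score, 0.11. The IL-2 call was lost without vehicle replicate 1 (0.321), vehicle replicate 2 (0.109) or NETs replicate 1 (0.133), as well as with the GC trend removed (0.127) and among protein-coding genes only (0.0771).

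The second question, raised by the culture conditions, was T cell fate. Foxp3, the lineage factor of regulatory T cells (ENSMUSG00000039521; chromosome X, 7579676 to 7595243), averaged 127 ± 26.2 CPM with vehicle and 145 ± 17.8 CPM with NETs (SD, n = 3 each). This log2 fold change of 0.20 (SE 0.13; edgeR adjusted p = 0.545) was no larger than the spread between replicates. The other regulatory genes of the panel had log2 fold changes of 0.13 for the IL-2 receptor chain Il2ra, 0.04 for the checkpoint receptor Ctla4, 0.10 for Ikzf2 and 0.27 for the cytokine Tgfb1 (SE 0.09; adjusted p = 0.258), none past the threshold. Within the regulatory T cell list, Capg was at 0.36, Ccr8 at 0.36 and Gpr83 at 0.23. The list had a median of 0.12 and a mean of 0.06 over 29 genes, with 21 above 0. Its camera adjusted p was 0.0347, and 0.681 with an estimated correlation. Adjusted over the list alone 0 genes were higher, and 0 by edgeR over all genes, with 2 at an unadjusted p under 0.05. The call was lost without vehicle replicate 1 (adjusted p = 0.335), vehicle replicate 2 (0.185), NETs replicate 1 (0.0777) or NETs replicate 2 (0.288), and among protein-coding genes only (0.0771), a fit added after seeing the data. Without vehicle replicate 3 the list's median was 0.22, and without NETs replicate 3 it was 0.18. The list score was −0.11, −0.11 and 0.22 in vehicle replicates 1 to 3 and 0.06, 0.20 and −0.06 in NETs replicates 1 to 3 (exact permutation p = 0.6).

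**Figure D3:**
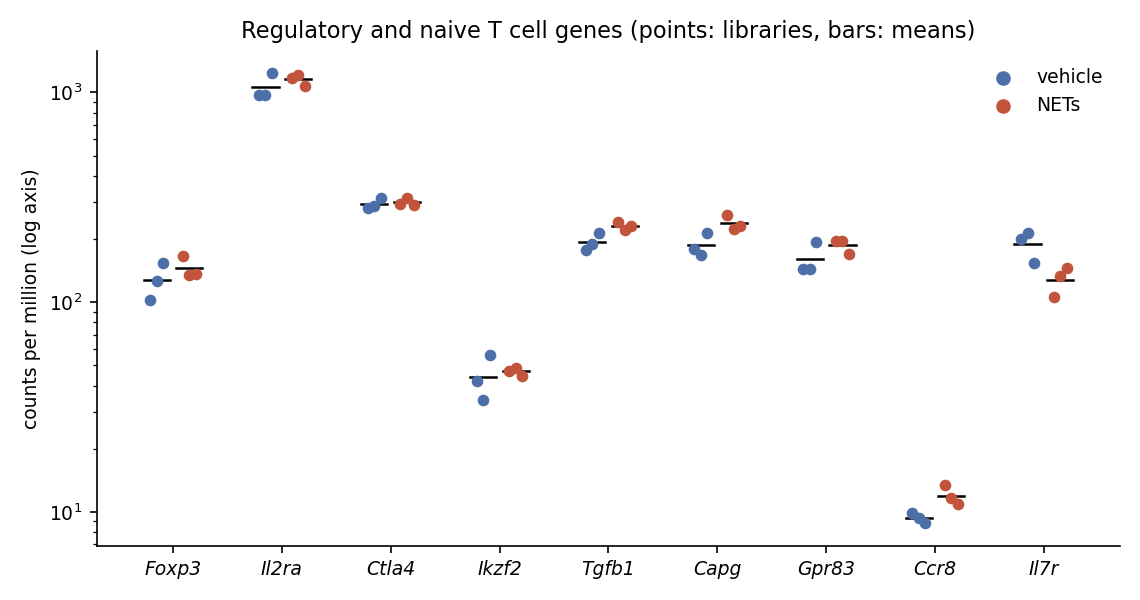
CPM on a log axis for regulatory and naive T cell genes, with a point for each library and a line at each group mean (n = 3). Foxp3 overlaps between groups, at 127 CPM on average with vehicle and 145 CPM with NETs, and Il7r averages 190 CPM with vehicle and 128 CPM with NETs.

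Cytokine transcripts that mark other helper fates were few. Ifng and Il17a had 0 reads in both groups, which allows up to 3 counts per group at this depth. Il10 had 1 read with NETs and 0 with vehicle, and Il4 had 26 reads with NETs and 22 with vehicle. Tbx21, the Th1 factor, was near 0.693 CPM with vehicle (log2 fold change −0.48, SE 0.69), and Gata3, the Th2 factor, at 90.1 ± 12.9 CPM with vehicle and 93.1 ± 10.7 CPM with NETs (0.06, SE 0.12). Il2 was at −0.41 (SE 0.35) and Gzmb at −0.04 (SE 0.18). The list medians were −0.09 for Th1 genes (17 genes), 0.06 for Th2 genes (7 genes; mean −0.04), −0.07 for Th17 genes (10 genes) and −0.14 for follicular helper genes (10 genes), with a camera adjusted p of 0.810, 0.857, 0.639 and 0.156. Adjusted over the list alone, Id3 was higher and Btla and Slamf6 were lower among follicular helper genes, 3 genes chosen after their values were seen, and 0 genes changed in the other 3 lists. Over all genes edgeR called 0 in each of the 4 lists, with 2, 1, 2 and 4 genes at an unadjusted p under 0.05. T cell activation genes had a median of 0.03 (camera adjusted p = 0.988, direction down), and inhibitory receptors a median of 0.04 with a mean of −0.07 (0.589, direction down). Cytotoxic genes had a median of −0.11 (0.495). Without NETs replicate 3 the activation list passed upward (adjusted p = 0.0249).

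Among sensors and metabolic regulators of the panel, Tlr2 was at −0.14 (SE 0.23), Tlr9 at 0.07 (SE 0.53), the adaptor Myd88 at 0.09 (SE 0.10), Myc at −0.12 (SE 0.08), Hk2 at 0.05 (SE 0.13) and Cpt1a at 0.11 (SE 0.08). Hif1a, the hypoxia-inducible factor, averaged 363 ± 20 CPM with vehicle and 297 ± 32 CPM with NETs, a log2 fold change of −0.28 (SE 0.09; edgeR adjusted p = 0.252). No panel gene passed over all genes or adjusted over the panel alone, where Tgfb1 and Hif1a had the smallest adjusted p, 0.0789. Tlr4 had 2 reads with vehicle and 6 with NETs, and Ppargc1a had 1 and 0.

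Lists of quiescence and innate signalling were also lower with NETs by camera with the preset correlation, and none passed with an estimated correlation (adjusted p = 0.641, 0.442 and 0.246 for the naive, interferon and NF-kB lists). Naive and quiescence genes had a median of −0.13 with 19 of 27 below 0. Il7r, the IL-7 receptor chain, averaged 190 ± 31.1 CPM with vehicle and 128 ± 20.7 CPM with NETs (log2 fold change −0.56, SE 0.14; edgeR adjusted p = 0.223), and the chromatin organiser Satb1 was at −0.17, while Treml2 was at 0.22. Type I interferon response genes had a median of −0.10 with 32 of 47 below 0, among them Gbp3 (−0.44), Gbp2 (−0.39) and the RNA sensor Ddx58 (−0.29). Genes of the TLR and NF-kB response had a median of −0.15 with 25 of 34 below 0. In that list Tnfaip3, a feedback inhibitor of NF-kB, was at −0.38, Nfkbiz, a nuclear regulator of NF-kB target genes, at −0.36, Il1b was at −1.78 from 1.45 CPM with vehicle, and Tnf was at 0.40. The camera adjusted p was 0.00964, 0.0184 and 0.00739 for the 3 lists. The members lower when adjusted over the list alone were 1 naive gene (Il7r), 1 interferon gene (Gbp4) and 0 NF-kB genes, and over all genes edgeR called 0 in each, with 3, 4 and 6 at an unadjusted p under 0.05. The exact permutation p of the scores was 0.3 for the naive and interferon lists and 0.1 for the NF-kB list. The naive call was lost without vehicle replicate 2 (0.410) or NETs replicate 2 (0.245), the interferon call without vehicle replicate 2 (0.142) or NETs replicate 1 (0.0514), and the NF-kB call without vehicle replicate 3 (0.105) or NETs replicate 3 (0.0508).

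Of the 8 marker lists of other cell types and CD4 T cells, neutrophil and B cell markers passed camera with the preset correlation, and neither with an estimated one (adjusted p = 0.316 and 0.269). S100a9 (ENSMUSG00000056071; chromosome 3, 90692632 to 90695721), a granulocyte gene, had 16, 24 and 20 reads in the NETs libraries and 0 in each vehicle library, at least 19.1-fold higher against a floor of 3 counts over the vehicle group (edgeR adjusted p = 0.170). That floor leaves out the counting error of the NETs reads, and the 95% counting interval of the ratio began at 15.1. Among other neutrophil genes tested, Mpo was at 0.34 (SE 0.43), Lcn2 at 0.44 (SE 0.67) and Padi4 at 0.14 (SE 0.32). The neutrophil list had a median of 0.34 over 5 genes, also with S100a9 at its bound, and a camera adjusted p of 0.025. S100a9 was the only one of these 5 genes at an unadjusted p under 0.05, and it was higher when adjusted over the list alone. With 0 vehicle reads, it entered the gene test through its NETs reads only. The list's call is therefore not evidence separate from the S100a9 reads. The neutrophil call was lost without vehicle replicate 3 (0.0503), NETs replicate 2 (0.167) or NETs replicate 3 (0.125), and when camera took the gene statistics in place of the counts (0.1). B cell markers had a median of −0.33 over 17 genes, with the transcription factor Pax5 at −1.11, Igkc at −0.82, Fcer2a at −0.67 and Blk at −1.65, all at 5.24 CPM or less with vehicle. Their camera adjusted p was 0.034. In the B cell list 0 genes passed when adjusted over the list alone or by edgeR over all genes, with 4 at an unadjusted p under 0.05. That call was lost without vehicle replicate 3 (0.143) or NETs replicate 2 (0.0786), and with a filter of CPM of at least 5 (0.977) or among protein-coding genes only (0.0771).

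The remaining marker lists did not pass. CD8 T cell markers had a median of −0.35 with 6 of 6 genes below 0 (camera adjusted p = 0.0523), and passed without vehicle replicate 1 (0.0306) or NETs replicate 3 (0.0293) with the replicate number as a block (0.0438), with no filter on low counts (0.00875) and with the length (0.0289) or GC trend (0.033) removed. Macrophage markers had a median of 0.10 over 16 genes (0.0655), where Lyz2 (lysozyme; log2 fold change 0.63, SE 0.16) was higher when adjusted over the list alone, and they passed without vehicle replicate 1 (0.0388), vehicle replicate 2 (0.0238) or NETs replicate 1 (0.021), with the block (0.0432) and with no filter (0.0243). Natural killer markers had a median of −0.17 and a mean of 0.25 over 4 genes (0.900, direction down), with Tyrobp higher over the list alone. Lyz2 and Tyrobp were named after their values were seen. Dendritic cell markers had a median of −0.10 (0.620), erythroid and platelet markers −0.14 (0.770) and CD4 T cell markers −0.04 (0.882). Of the 3 lists fixed as signs of RNA quality, the replication-dependent histones passed, as given above, while immediate early genes induced by cell handling had a median of −0.14 (0.669) and nuclear-retained and small RNAs −0.08 (0.810).

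**Figure D4:**
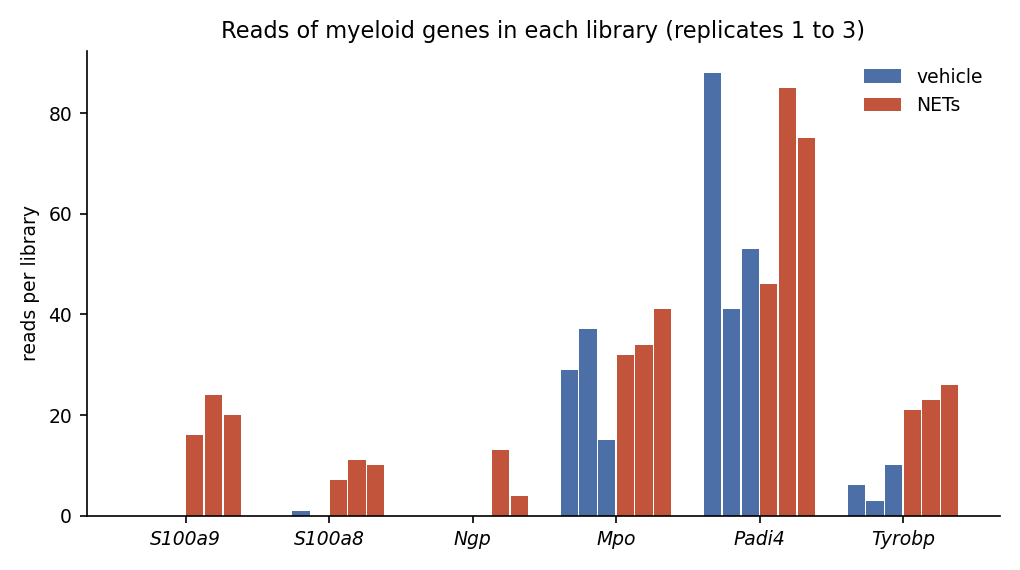
Reads per library (y axis) of 6 myeloid genes, with bars for vehicle and NETs replicates 1 to 3. S100a9 has 16 to 24 reads in the NETs libraries and 0 in the vehicle libraries, while Mpo and Padi4 overlap between groups.

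In all, 27 of 48 lists passed camera with the preset correlation, 21 upward and 6 downward. With an estimated correlation 0 passed, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.246, and the median estimated correlation was 0.132. By fry 0 passed, with 19 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0779. The lists called without any single library and under each scaling, filter, block and trend setting numbered 16, among them oxidative phosphorylation and its 5 complexes, the proteasome and DNA replication. Oxidative phosphorylation shares its genes with these complexes, and the TCA cycle shares Sdhd and Sdha with complex II. Such lists are not independent, so both counts of lists include the same genes more than once.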

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

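Both tests in this part, on read scatter and on the other neutrophil markers, were chosen after the S100a9 reads had been seen. Among the genes too little read for the gene test, S100a8 and Ngp had more reads with NETs than with vehicle. S100a8, the partner of S100a9 in calprotectin and its neighbour on chromosome 3, had 28 reads over the NETs libraries and 1 over the vehicle libraries, a ratio of 26.8 (95% counting interval 4.43 to 1095). Ngp, a granule protein gene of neutrophils, had 17 reads with NETs and 0 with vehicle, at least 5.42-fold higher against a floor of 3 counts over the group, and the 95% counting interval of the ratio, which also covers the error of the NETs reads, began at 3.95. Below the filter, 53 genes had at least 3 reads in each NETs library and at most 3 over the vehicle libraries, and 44 genes showed the mirror image, a difference that was not tested. S100a8 was among the 53 genes and Ngp was not, so the Ngp reads did not reach 3 in each NETs library.

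The S100a9 and S100a8 reads were weighed against read scatter and against neutrophil RNA carried in with the NETs. Among the 19 other ways of taking 3 of the 6 libraries, 1 gene (Gpx5, named after its values were seen) had at least 16 reads in each of 3 libraries and 0 in the others, as S100a9 did in the real choice. The minimum of 16 is the lowest S100a9 count itself, so the real choice was bound to hold 1 gene. Gpx5 was read in vehicle replicate 3 and NETs replicates 1 and 2, which form 1 side of a split with 43 called genes. The rule first compared the real count with the highest of the other choices, by which scatter would have held, and was changed to their mean once that outcome was known, so scatter stays open. If neutrophil RNA came with the NETs, the other 23 neutrophil markers might be higher too. Of these markers, 4 were read enough to test in these T cells. The 23 markers stood at 10.5 ± 2.5 CPM with NETs and 9.17 ± 0.859 CPM with vehicle (SD, n = 3 each). The ratio was 1.14 (exact permutation p = 0.4, counting interval 1.007 to 1.29), with NETs replicate 1 at 7.63 the lowest library. The markers had 555 reads with NETs and 465 with vehicle, of which Padi4 had 182 and Mpo 81. Against that background a carry-over of the size of the S100a9 and S100a8 reads could go unseen. How far it would raise these markers is not known either, so the test cannot decide. Carry-over of neutrophil RNA, a few neutrophils left by the selection of naive CD4+ cells, and expression by the T cells themselves therefore cannot be told apart at these counts.

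Other myeloid genes are given as values. Tyrobp had 70 reads with NETs and 19 with vehicle, a ratio of 3.52 (95% counting interval 2.10 to 6.20), and Lyz2 had 1902 and 1202, a ratio of 1.51 (1.41 to 1.63).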

How the results depend on the processing

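Removal of the GC trend, alone or with the length trend, the use of gene statistics with no trend removed and the fit on protein-coding genes only were chosen after results had been seen. The edgeR count of 0 genes, with 1776 at an unadjusted p under 0.05, held with DESeq2 size factors, upper-quartile scaling, the stricter filter and protein-coding genes only, and limma-trend with no filter on FPKM also gave 0. A minimum log2 fold change of 1 could not add to a count of 0. With no filter on low counts edgeR called 322 genes (192 higher, 130 lower). DESeq2 called 130 of the 8241 genes it gave an adjusted p. Limma-voom called 1 (S100a9), and limma-trend 1 at each pseudocount (Gm24270, named after its values were seen). Leaving out 1 library gave from 0 to 405 genes: 405 without vehicle replicate 3, 2 without NETs replicate 2 (Lsm4 and Gm23935, named after their values were seen), 1 without NETs replicate 1 (Gm23935) and 0 without any of the other 3. The cause was not tested.

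The count of lists past camera stayed between 22 and 30 in every scaling, filter, block, trend and left-out setting. It was 0 with an estimated correlation and 0 with fry, with 8 and 19 lists at an unadjusted p under 0.05. Both of these tests allow for genes of a list that vary together between libraries. The oxidative phosphorylation median of 0.23 lay between 0.20 and 0.27 in all settings and kept its call in all but those same tests, where the median is unchanged by construction (adjusted p = 0.246 with an estimated correlation and 0.0793 with fry). The regulatory T cell median of 0.12 ranged from 0.049 (without vehicle replicate 2, adjusted p = 0.185) to 0.22 (without vehicle replicate 3, 9.67e-05) as libraries were left out. Its adjusted p rose to 0.335 without vehicle replicate 1, 0.0777 without NETs replicate 1, 0.288 without NETs replicate 2, 0.681 with an estimated correlation and 0.540 with fry, and was 0.0771 among protein-coding genes, where the median was 0.10. The cause was not tested. Cytosolic ribosomal proteins went from 0.05 to −0.016 (adjusted p = 0.243) with length and GC trends removed; the cause was not tested.

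Of the 124 tested named genes, 62 passed in at least 1 setting, 54 with no filter, 52 without vehicle replicate 3, 27 by DESeq2 and 1 by limma-voom. In some setting 9 of them changed sign, none while past the threshold.

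Fitting the replicate number as a block gave 0 genes at the threshold (edgeR), 29 lists, an oxidative phosphorylation median of 0.23 and a regulatory T cell median of 0.12 (adjusted p = 0.0359). It put CD8 T cell and macrophage markers past the threshold and changed no other call. The deviations of same-numbered libraries correlated at −0.03, −0.06 and −0.18, and no library correlated best with its own number. This check detected no pairing by number. With so few libraries it cannot exclude that equal numbers share an animal or a day.

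Depth limits the genes of low count: Ifng, Il17a, Il10, Tlr4 and Ppargc1a had 6 reads or fewer per group, and Tbx21 had a standard error of 0.69.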

Other observations

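In this part, the removal of the GC trend, the tests on non-coding genes and the test of exchanged labels were chosen after results had been seen; the bounds for the length and GC tests were set after the trends over all genes had been seen but before the corrected list medians were. Further fixed lists did not pass camera. Hypoxia response genes went both ways, with a median of −0.07 over 27 genes (adjusted p = 0.288) and 4 genes past the threshold adjusted over the list alone, Ldha, Ddit4 and Higd1a higher and the growth factor gene Vegfa lower, although edgeR called 0 over all genes, with 10 at an unadjusted p under 0.05. That list passed downward without NETs replicate 2 (0.0134) and with the replicate block and the length trend removed (0.0468). TGF-beta response genes had a median of 0.14 over 19 genes (0.0658), with Id3 (0.49, SE 0.13) higher over the list alone, and passed upward without vehicle replicate 2 (0.0302), vehicle replicate 3 (0.0419) or NETs replicate 1 (0.0171) and with no filter on low counts (0.00776). Ddit4, Higd1a, Vegfa and Id3 were named after their values were seen.

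Chemokine and cytokine genes had a median of 0.04 and a mean of −0.11 over 24 genes (camera adjusted p = 0.810, direction up), and passed upward with a filter of CPM of at least 5 (0.0451). Heat shock genes had a median of 0.03 and a mean of −0.08 (0.857, direction up), p53 and apoptosis genes a median of −0.01 and a mean of 0.02 (0.900, direction down), and TLR and DNA sensor genes a median of −0.04 and a mean of 0.01 (0.979, direction down). In these 4 lists 0 genes passed when adjusted over the list alone.

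Non-coding genes of the lincRNA, antisense, intronic and TEC (a provisional annotation) classes had a median log2 fold change of −0.27, with 763 of 1095 below 0. The share of counts in lincRNA, antisense and TEC genes was 0.754% ± 0.0576 with vehicle and 0.673% ± 0.0186 with NETs (SD, n = 3 each; exact permutation p = 0.1), with p = 0.2 for the lincRNA and for the antisense class by the same exact test. By class the medians were −0.45 for 46 sense-intronic genes, −0.30 for 280 TEC genes, −0.25 for 369 lincRNAs and −0.20 for 400 antisense genes. Protein-coding genes matched on expression had medians from −0.07 to 0.03 in 100 draws. With the GC trend removed the non-coding median was −0.24, and among the 10 splits of the libraries the real one gave the largest absolute median, 0.27, against 0.23 for the next. Genes of the miRNA class took 0.0404% ± 0.000505 of counts with vehicle and 0.0793% ± 0.0273 with NETs (SD, n = 3 each; exact permutation p = 0.1). The rise was not shared across the class, as 13 of 23 tested genes lay above 0 and 10 below, with a median of 0.14.

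The higher oxidative phosphorylation genes are shorter than the average gene (median length 1701 against 3937.5 bases), and across genes the log2 fold change correlated with length at rho = −0.10 and with transcript GC content at rho = 0.21. Removing the length trend left the list's median at 0.20 and removing the GC trend left it at 0.24. Neither removal could have brought the median near 0, so these outcomes are no separate test. The list's median GC content, 50.024%, was close to the 49.551% of all genes. With all genes in 10 groups by length, no group had a median log2 fold change above 0.056. The values show only that the trends over all genes do not reach 0.23 at this list's length and GC content. In 1 of the 10 splits of the 6 libraries, the real one, the median was as far from 0 as 0.23, and the highest other split gave 0.15; 27 lists passed camera in the real split, also as many in 1 of 10, against 21 in the highest other. With 10 splits a share under 0.05 cannot be reached. An effect of the NETs on the T cells or a shift in the mix of cells in the cultures may account for the shift. So may a difference in how the cultures were handled or in RNA quality, and the design does not separate these. The exact permutation p of the scores was also 0.1 for neutrophil, macrophage, B cell and CD8 T cell markers and for the replication-dependent histones. It ran from 0.2 to 0.9 for the remaining marker and RNA quality lists.

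The real split gave 0 genes at the edgeR threshold, so that all 10 splits gave as many tells nothing by itself, but the highest other, at 43 genes, points to a structure of the samples other than the groups. It came from setting vehicle replicates 1 and 2 and NETs replicate 3 against vehicle replicate 3 and NETs replicates 1 and 2. Of these, 26 genes were higher in the latter libraries, such as Cd24a (0.90), Marcksl1 (0.87), Odc1 (0.73) and Irf4 (0.65), and 17 were lower, such as Cd7 (−1.10) and Pik3ip1 (−0.67), named after their values were seen; 42 of the 43 had the same sign in the NETs contrast, which places 4 of the 6 libraries alike, and 9 were among the 405 genes called without vehicle replicate 3. Exchanged labels of vehicle replicate 3 and NETs replicate 3 could give this. The oxidative phosphorylation score of NETs replicate 3 exceeded that of vehicle replicate 3 by 0.18. That list was taken for this test after it was seen to separate the labelled groups, so the difference cannot count against an exchange. S100a9 had 20 reads in NETs replicate 3 and 0 in vehicle replicate 3, but it too was picked because it separates the labelled groups. Gpx5 showed the opposite, with 35 reads in vehicle replicate 3, 43 and 22 in NETs replicates 1 and 2, and 0 in the other libraries. The regulatory T cell score of NETs replicate 3 also differed from that of vehicle replicate 3 by −0.28. With 3 libraries a group an exchange and other differences between the cultures, such as in activation state, which was not tested, cannot be told apart.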
